A study of Caulobacter vibrioides CB15 with 4 samples.

How the data were processed

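RNA from Caulobacter was compared on 4 Agilent arrays with 2 colours each. On 2 depletion arrays, per the labels, a strain whose sciP gene depends on xylose supplied both channels: swarmer cells re-isolated after 1 cell cycle in glucose (Cy3) and in xylose (Cy5). On 2 overexpression arrays, per the labels, wild-type cells with an empty vector (Cy3) were set against wild-type cells carrying sciP behind a xylose-inducible promoter on a plasmid (Cy5), both after 2 h of xylose. The dyes were not swapped in either experiment, so a gene's dye effect cannot be told apart from its change within 1 experiment. The labels speak of duplicates without naming separate cultures, so the p-values measure the spread between these arrays, which may be technical. Each experiment lay wholly on its own slide and scan, so slide and experiment cannot be told apart.

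The deposited scanner files give spot intensity in each channel on a linear scale, with a local background intensity, per the file headers from Agilent Feature Extraction 9.1.3.1. Per the file headers, spatial and multiplicative detrending were on and local background subtraction was off in the processed signals, from which the software wrote a log10 ratio of red over green. The series value table deposited by the authors holds the same log10 ratios: taken in row order, they differed from the scanner files' ratios by at most 4.99e-05, so scale, centring and direction are those of the software. Their medians were -0.0094 and -0.0030 on the depletion arrays and 0 on both overexpression arrays.

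Each array held 45206 spots, of which 43979 were not controls. The probes are 60 bases long and tile a window per gene that begins upstream of the gene. All 3748 sense probes that cover window position 400 carried ATG, GTG, TTG or CTG there, so position 400 was taken as the start codon. A gene's value was the mean of its sense probes lying wholly inside the coding part, after the spots of a probe were averaged. Probes were 1 to 3 per gene with a median of 3. Only the first part of each coding region was therefore measured. Left out were 4396 reverse-complement probes, 960 probes whose sequence stood under the name of more than 1 gene, 1162 probes of other name classes, and upstream probes. Of 3595 genes with a value on all 4 arrays, 3416 matched a locus tag in the RefSeq table of assembly ASM690v1 and 727 had a symbol of their own there; other genes keep the locus tag that the files give. No build is named in the files, and the table was used only for names, neighbours and coding length. Coding probes of a gene differed by over 2 log2 units for 49 genes on depletion and for 19 on overexpression, out of 3513 genes with more than 1 probe.

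The mean foreground and median background intensities were corrected by normexp with an offset of 50, normalized by loess within each array with control spots at weight 0, and expressed as log2(Cy5/Cy3), with limma 3.58.1 in R 4.3.3. Spots with an outlier flag were left out (223 among coding probes over the 4 arrays). The dim-spot filter asked for a signal well above background in at least 1 channel on at least 2 arrays. It removed 0 coding probes, as did the stricter filter, so neither filter tests anything. The flag was set for all 43979 non-control spots and cannot show whether a channel lay near the negative controls. Whether a large fold is a bound for dimness was not tested. Saturation was flagged at 5 spots of coding probes, all in Cy5 on overexpression; they were kept. Saturation was flagged for 0 coding probes on both arrays of an experiment, so no value rests on saturated spots alone. Saturation in Cy5 can lower a ratio, so the overexpression values of CC0367, CC0486, CC1007 and CC1750 may be too low. Median signals lay between 1845 and 4186 against 75.5 to 130 for negative controls. The number of arrays limits the precision.

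Both experiments entered 1 limma fit (lmFit, eBayes), with 1 coefficient each and 2 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes were called per gene against a log2 ratio of 0. Overlap between experiments was tested with Fisher's exact test, two-sided. Of the 16 gene lists fixed before the data were examined, 14 had at least 3 measured members and were tested with camera (preset correlation 0.01, adjusted over the lists), with sciP left out; the chemotaxis and TonB-dependent receptor lists had 0 members by symbol or locus tag. On simulated arrays with 3595 genes and 50 changed genes per size, the fit recovered 82% of log2 changes of 0.5 on depletion and 88% on overexpression, 98% of changes of 1 in each and 100% of changes of 2 in each. False calls numbered 8 on depletion and 10 on overexpression. The simulated noise was independent between genes, took its spread from the fit itself and held no dye effect. It checks the procedure and does not measure recovery in these data.

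Named genes followed a rule set before the data were examined: sciP, the 10 strongest genes per direction with a mean change of at least 2-fold and the same sign on both arrays, a fixed set of cell cycle and flagellar genes, up to 4 members per list, and the 10 strongest opposed genes. The text prints the leading members of each part. CC2045, in the fixed set, had 0 probes of the class used. Alternatives covered background correction, the software's own log ratio and the value table, median centring in place of loess, scaling between arrays, both filters, the median over probes, outlier spots, separate fits, replicate number as a block, an intensity trend with a robust prior, GC content, each array left out, and an estimated correlation in camera. Others were chosen after seeing the data: probes that overlap the start codon, all sense probes of a window, the depletion sign turned, and a crossed pairing. Figures were drawn with matplotlib.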

Results

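Transcript levels were measured in Caulobacter, a bacterium whose flagellated swarmer cells stay in G1 before they turn into stalked cells and replicate. sciP encodes a small protein known to restrain transcription driven by CtrA, the master cell cycle regulator. The experiments asked which genes respond when sciP is depleted in swarmer cells or overexpressed in wild-type cells. There were 2 arrays per experiment and 3595 genes with a value on all 4. Across genes the log2 ratios of the 2 depletion arrays correlated at 0.95 (Pearson) and 0.79 (Spearman). Those of the 2 overexpression arrays correlated at 0.93 (Pearson) and 0.81 (Spearman). Genes are not independent replicates.

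The targeted gene was read first. On overexpression sciP RNA was 19.2-fold higher in the sciP plasmid strain than with the empty vector, with a log2 ratio of 4.26 ± 0.03 (SD, n = 2; limma adjusted p = 1.24e-07). On depletion its log2(Cy5/Cy3) was -5.14 ± 0.09 (SD, n = 2; limma adjusted p = 9.84e-08), so that the channel labelled xylose held 35.4-fold less sciP RNA than the channel labelled glucose. This goes against the channel labels, under which glucose is the depleted condition in Cy3; the array titles name glucose first and xylose second, without saying which dye stood over which. Depletion values are therefore given as Cy5 over Cy3, that is the channel labelled xylose, which held less sciP RNA, over the channel labelled glucose. With the labels taken as written, every depletion direction below reads in reverse as a glucose over xylose change. Within the probe window of sciP, the 3 coding probes lay between -6.09 and -3.56 on depletion. The 7 probes wholly upstream of its start codon lay between 2.51 and 6.28, and the neighbouring gene CC0902 (flgE) was higher in Cy5.

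**Figure D1:**
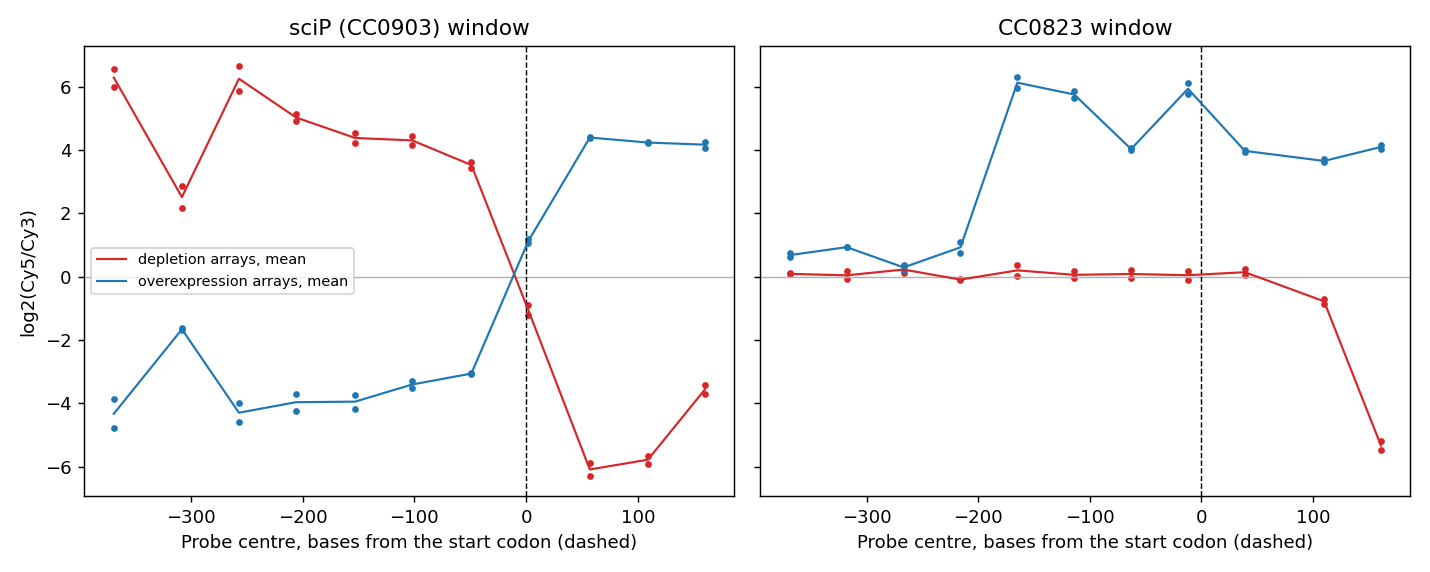
Probe log2(Cy5/Cy3) against the distance of the probe centre from the start codon (bases) for the windows of sciP and CC0823; points are single arrays, lines the mean of 2 arrays per experiment. In the sciP window the sign turns at the start codon in both experiments, with coding probes near 4.23 on overexpression and -5.78 on depletion (medians); in the CC0823 window the depletion arrays depart from 0 only at the last coding probes, to -5.33.

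On the depletion arrays the genes of flagellar assembly stood highest in the channel with less sciP RNA. flgE, the flagellar hook protein, was 111-fold higher there (log2 6.79 ± 0.27, SD, n = 2; limma adjusted p = 9.57e-07), and the flagellin gene fljL was 59.5-fold higher (log2 5.89 ± 0.05). The rod genes flgG and flgF followed at 5.06 ± 0.34 and 4.90 ± 0.09. Next were the flagellin fljK at 3.90 ± 0.02, the L-ring gene flgH at 3.56 ± 0.67 and the rod gene flgC at 3.45 ± 0.26. The values of fljK in both experiments rest on 1 probe. Genes without a symbol among the 10 strongest were CC0901 at 4.71, CC0794 at 4.24 and CC2175 at 3.49. All 28 measured genes of the flagellum list were higher in that channel, also when adjusted over the list alone, with a median of 1.90. camera called the list (adjusted p = 4.19e-23; adjusted p = 0.152 with an estimated correlation).

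Other genes of the swarmer cell surface and of CtrA control moved the same way. All 3 genes of the pilus list were higher in the channel with less sciP RNA, the pilus assembly gene cpaB at 2.29 ± 0.03, CC2948 at 1.63 ± 0.32 and cpaE at 0.59 ± 0.07 (SD, n = 2 each); the list had adjusted p = 0.000814 in camera and adjusted p = 0.16 with an estimated correlation. Of 8 genes of the holdfast, the adhesive at the cell pole, 7 were higher and 1 lower (hfiA, an inhibitor of holdfast synthesis, at -0.26, named after its value was seen and not called without either array), with hfsF at 2.07, hfaA at 1.83 and hfaB at 1.76 (list adjusted p = 0.000138; adjusted p = 0.152 with an estimated correlation). All 14 genes of the CtrA-activated list are also in other lists, so its result is not separate from theirs. The flagellum list holds 6 of them, pilus 2, cell cycle regulators 4 and division and cell wall 2. Of the 14, 12 were higher and 0 lower, and 13 were higher when adjusted over the list alone. Here fliJ stood at 2.40 and the response regulator gene divK at 2.37 (camera list adjusted p = 3.34e-10, and adjusted p = 0.152 with an estimated correlation). ctrA itself was 2.16-fold higher (log2 1.11 ± 0.19, limma adjusted p = 0.000164), fliF 2.79-fold (1.48 ± 0.42) and CC3315 2.46-fold (1.30 ± 0.01). The methyltransferase gene ccrM had values of opposite sign on the arrays (-0.45 and 0.41) and was not called (limma adjusted p = 0.943). The replication initiator gene dnaA lay at -0.13 ± 0.01 and was not called.

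The cell cycle regulators went both ways on depletion. Of 21 members, 7 were higher in the channel with less sciP RNA, 9 when adjusted over the list alone, and 7 lower; the list's median was -0.02 while its mean was 0.41, and camera did not call it (adjusted p = 0.323, and 0.0223 without the first depletion array). CC2462 at 2.22, CC1963 at 1.52 and cpdR, a response regulator gene of CtrA proteolysis, at 1.49 were among the higher ones. The early stalked phase markers, chosen as a possible sign of stalked cells among the isolated swarmers, were lower in that channel for 3 of 4 genes: ftsZ at -0.39 ± 0.01, gcrA at -0.38 ± 0.20 and spmX at -0.37 ± 0.28. Whether the mix of cells lowered them was not tested. The list's adjusted p was 0.0266 in camera, and adjusted p = 0.434 with an estimated correlation. Without the first depletion array the list's adjusted p was 0.0669 and gcrA, at -0.23, was not called; without the second the list had 0.0771 and spmX, at -0.17, was not called. With median centring in place of loess the list had 0.111 and neither ftsZ, gcrA nor spmX was called.

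Genes of sugar use separated the channels as well. Of 6 xylose use genes, 5 were lower in the channel labelled xylose and 0 higher, with a median of -1.49: xylB, the xylose dehydrogenase gene, at -3.15 ± 1.29, CC0823 at -1.99 ± 0.01, CC0822 at -1.52 ± 0.05 and the xylonate dehydratase gene xylD at -1.45 ± 0.06 (list adjusted p = 2.14e-05; adjusted p = 0.152 with an estimated correlation). The 3 coding probes of CC0823 disagreed, from 0.14 to -5.33, and the 6 probes upstream of CC0822 had a median of -4.87. All 4 genes of the Entner-Doudoroff pathway of glucose use were higher in the channel labelled xylose, edd at 1.62 ± 0.10, pgl at 1.28 ± 0.09, zwf at 1.01 ± 0.08 and glk at 0.99 ± 0.05 (list adjusted p = 7.21e-05; adjusted p = 0.152 with an estimated correlation). Carbon source and sciP change together in this comparison.

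camera called none of the remaining 6 lists on depletion (adjusted p from 0.0808 to 0.665); of all genes, 25.9% were past the threshold there. For division and cell wall, 3 of 23 genes were higher and 4 lower, with murD at -0.60 and ftsQ at 0.55; the list's median (0.01) and mean (-0.01) differed in sign. For replication and chromosome, 2 of 16 were higher and 4 lower, led by the gyrase gene gyrA at -0.78. Ribosomal proteins had 8 of 42 higher and 2 lower, with rpmG at 0.45 and rplK at 0.43; this list was called with median centring (median 0.39, adjusted p = 4.24e-07) and with the software's log ratio. For respiration and ATP synthase, 3 of 21 were higher and 2 lower, including ccoN at 0.36, for chaperones 2 of 11 were higher (groL at 0.55), and for SOS and DNA repair 3 of 11 were higher and 2 lower (recA at -0.43, ruvB at 0.41).

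Outside the lists, the strongest genes in the channel with more sciP RNA were CC0167 at -3.89 ± 0.52, CC3501 at -3.53 ± 0.33, CC3500 at -2.86 ± 0.82, CC1777 at -2.75 ± 0.62 and CC1778 at -2.62 ± 0.55 (SD, n = 2 each). All of these were lower in Cy5 on overexpression too, at -3.40, -2.05, -1.12, -1.49 and -1.07 in that order. There Cy5 was the channel with more sciP RNA, so they did not follow its level in both experiments. In all, limma called 932 of 3595 genes on depletion, 545 higher and 387 lower in Cy5; 153 were higher and 28 lower by at least 2-fold. With median centring in place of loess the calls were 408, of which 78.7% rather than 58.5% were higher in Cy5. Without the first or the second depletion array there were 621 and 613.

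On overexpression of sciP, flagellar genes were again among the strongest changes and now fell. flgE fell 33.3-fold (log2 -5.06 ± 0.45, SD, n = 2; limma adjusted p = 3.39e-06), fljK 12.2-fold (-3.61 ± 0.30), flgG 9.91-fold (-3.31 ± 0.35), flgF 9.43-fold (-3.24 ± 0.40) and fljL 9.32-fold (-3.22 ± 0.21). Of the 28 flagellum genes, 27 fell and 0 rose, and 28 fell when adjusted over the list alone; the median was -1.69 (list adjusted p = 4.68e-15; adjusted p = 0.362 with an estimated correlation). CC0682 at -4.22 ± 0.42, CC3218 at -4.08 ± 0.08, CC0901 at -4.03 ± 0.29, CC0559 at -3.88 ± 0.53 and CC0167 at -3.40 ± 0.54 were the other strong falls.

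Several cell cycle genes fell as well. ctrA fell 5.5-fold (log2 -2.46 ± 0.19, SD, n = 2; limma adjusted p = 6.35e-06), fliF, the base of the flagellar motor, 4.21-fold (-2.07 ± 0.38), ccrM 3.15-fold (-1.65 ± 0.13), CC3315 2.38-fold (-1.25 ± 0.02), ftsZ, the division ring gene, 2.32-fold (-1.22 ± 0.02), CC2462 2.22-fold (-1.15 ± 0.05), divK 2.07-fold (-1.05 ± 0.06) and gcrA 1.52-fold (-0.61 ± 0.18). dnaA lay at 0.11 ± 0.01 and was not called. Of 21 cell cycle regulators, 11 fell and 2 rose (chpT at 0.26 and tipN at 0.23, named after their values were seen; median -0.61), with adjusted p = 0.0524 for the list in camera and adjusted p = 0.408 with an estimated correlation. The list was past the threshold under other settings, among them median centring (adjusted p = 0.00133) and without the second overexpression array (0.029). In the CtrA-activated list 12 of 14 fell and 1, CC2948, rose, with fliJ at -2.03 and cpaB at -1.94 (list adjusted p = 3.81e-06; adjusted p = 0.362 with an estimated correlation). Holdfast genes fell for 6 of 8, or 7 of 8 when adjusted over the list alone, with hfaA at -1.86 ± 0.25, hfaB at -1.70 ± 0.07 and the inhibitor gene hfiA at -0.69 ± 0.02 (list adjusted p = 0.000874; adjusted p = 0.362 with an estimated correlation).

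Of the 3 pilus genes, cpaB and cpaE (-0.48 ± 0.14) fell while CC2948 rose to 0.62 (list adjusted p = 0.504). With all sense probes of the window, a setting chosen after seeing the data, the list was called (median -1.39, adjusted p = 0.0432). Among early stalked phase markers ftsZ and gcrA fell and hemE rose to 0.44 ± 0.05 (list adjusted p = 0.723).

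**Figure D2:**
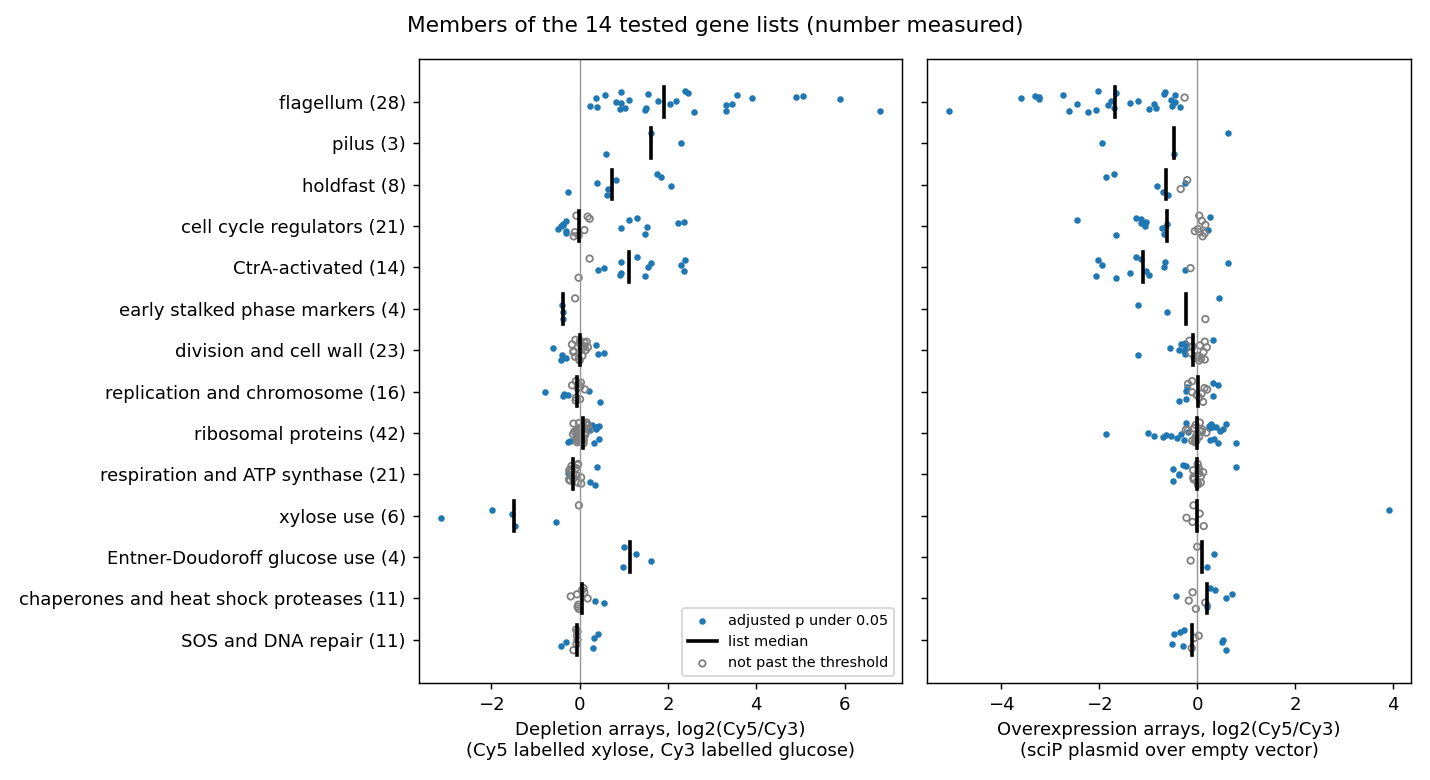
Log2(Cy5/Cy3) of each member of the 14 tested gene lists on the depletion arrays and on the overexpression arrays (mean of 2 arrays); filled points passed the gene threshold, bars are list medians. The flagellum list has a median of 1.90 on depletion and -1.69 on overexpression, while replication and chromosome genes have medians of -0.06 and 0.02.

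Few genes rose by much on overexpression: 11 rose and 155 fell by at least 2-fold. The largest rises were CC0824 at 5.13 ± 0.03 (35.1-fold), sciP, and CC0823 at 3.91 ± 0.03 (15.0-fold; SD, n = 2 each; limma adjusted p = 6.07e-08 for CC0824 and 1.24e-07 for CC0823). The next were CC0298 at 1.41, CC1550 at 1.28, CC2258 at 1.24 and CC1822 at 1.23. CC0823 was the only one of 6 xylose use genes past the threshold. The list's median was -0.01, its mean 0.62 and its adjusted p in camera 0.442. The rise of CC0823 was measured at its first part only. The 6 probes upstream of CC0822, in the 3' part of CC0823, had a median of 0.061 on overexpression. Ribosomal protein genes went both ways, 14 of 42 up and 11 down, with rpsQ at -1.87 ± 0.21, rplE at -1.01 ± 0.05 and rpsO at 0.80 ± 0.05 (list adjusted p = 0.504, and 0.017 with median centring); camera ranked this list upward although its median was -0.01. Chaperone genes rose for 6 of 11 and fell for 1, the protease gene lon at -0.44, with rpoH, the heat shock sigma factor gene, at 0.70 and clpB at 0.58 (list adjusted p = 0.112). In SOS and DNA repair 3 of 11 rose and 5 fell, with recF at 0.60 and lexA at -0.51 (list adjusted p = 0.723). Division and cell wall genes fell for 9 of 23 and rose for 1 (ftsY at 0.33, named after its value was seen), replication genes rose for 3 of 16 and fell for 4, respiration genes rose for 1 of 21 (atpD at 0.79) and fell for 6, and Entner-Doudoroff genes rose for 2 of 4 (pgl at 0.35 and glk at 0.20); camera called none of these 4 lists, with adjusted p from 0.504 to 0.723. Without the second overexpression array neither pgl (0.27) nor glk (0.13) was called, and without the first glk (0.26) was not. In all, limma called 1556 of 3595 genes on overexpression, 606 up and 950 down. With median centring there were 580, of which 25.7% rather than 38.9% were up, and with scaling between arrays 969.

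Set side by side, the experiments shared 540 genes past the threshold. The strongest excess was among genes higher in the depletion channel with less sciP RNA and lower on overexpression: 285 genes against 144 for independent lists (Fisher's exact test, two-sided, p = 5.39e-45, adjusted over the 4 direction pairs 2.16e-44), 81 of them by at least 2-fold in both. The pair lower on depletion and higher on overexpression held 61 genes against 65.2 (Fisher's exact p = 0.566, adjusted 0.566). Lower in both were 127 against 102 (Fisher's exact p = 0.00334, adjusted 0.00445), and higher in both were 67 against 91.9 (Fisher's exact p = 0.00186, adjusted 0.00372). These tests take genes as independent and the 2 call lists as separate. Both lists rest on 1 fit with a shared spread per gene, and runs of neighbouring genes moved together. The p-values and expected counts are therefore descriptive. Genes on opposite sides of the dyes thus numbered 346; with the depletion labels taken as written, the genes that moved oppositely are the other 194. With median centring the latter count was 43. The mean changes correlated across genes at -0.42 (Pearson) and -0.10 (Spearman) as Cy5 over Cy3, and at 0.42 (Pearson) with the labels as written; over all non-control probes the deposited log ratios of a depletion and an overexpression array correlated between -0.32 and -0.13. Of the 28 flagellum genes, 27 were among the 285, as were 10 of 14 CtrA-activated and 5 of 8 holdfast genes. With sciP itself (-5.14 and 4.26) left out, the 10 genes with the largest changes on opposite sides of the dyes were flgE, CC0901, fljK, flgG, flgF, fljL, flgH (3.56 and -2.74), flgK (3.30 and -2.62), flgC (3.45 and -2.46) and CC2582 (2.58 and -2.33).

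**Figure D3:**
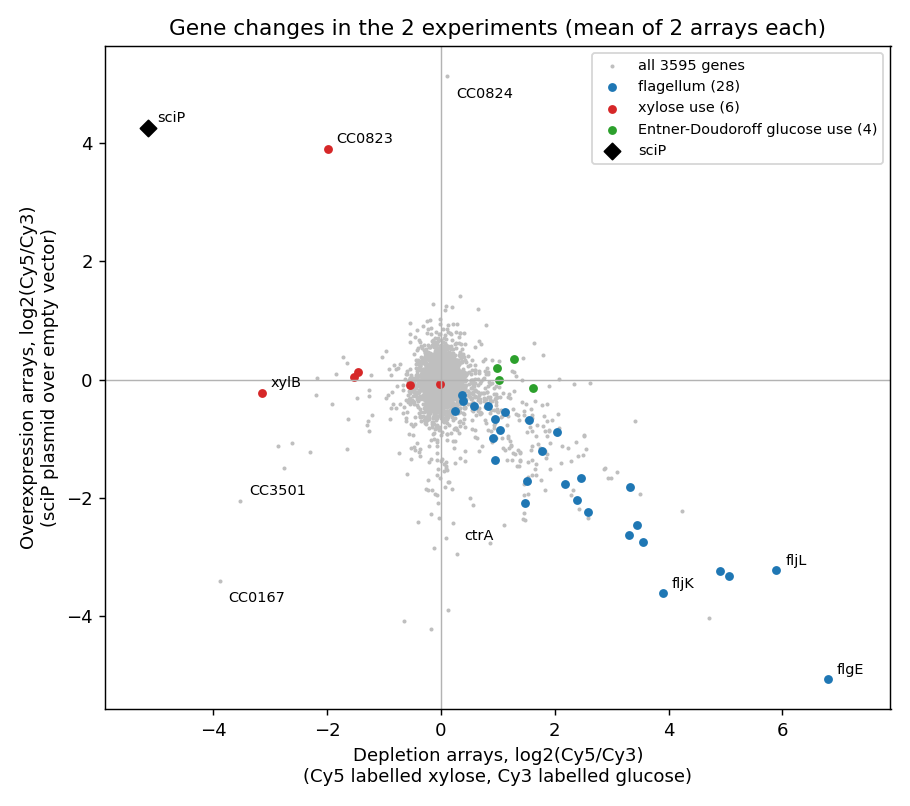
Mean log2(Cy5/Cy3) of each of 3595 genes on the depletion arrays (horizontal) and the overexpression arrays (vertical), with 3 gene lists and sciP marked. Flagellum genes lie toward the lower right, from 0.25 to 6.79 on depletion and -5.06 to -0.26 on overexpression, and sciP lies at the upper left (-5.14 and 4.26).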

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

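The test of probe GC content was set out before its result was seen; the other tests in this part were chosen after the results were seen.

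The reverse-complement probes, which the comparisons of the report leave out, numbered 4396, of which 40 had a sequence under more than 1 gene and 20 an outlier flag. Of the remaining 4336, 263 on depletion and 84 on overexpression had an absolute log2 ratio above the 99th percentile of the negative controls (0.427 and 0.956), where the limit's own definition gives 43.4. limma called 207 of them on depletion and 803 on overexpression. Across probes their ratios correlated with those of the sense probe at the same place at 0.22 and 0.28. Whether their signal comes from RNA of that strand was not tested.

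sciP went against the channel labels on depletion, at -5.14 for the channel labelled xylose over that labelled glucose. Channels that followed the labels with sciP alone out of place would put xylose use genes higher in the channel labelled xylose; their median there was -1.49 (SD over 6 members 1.10), which argues against it. Exchanged labels would put glucose use genes higher in that channel, and the Entner-Doudoroff median was 1.15 (SD over 4 members 0.29), in line with an exchange. The array titles name glucose before xylose, which read as Cy5 over Cy3 would put glucose in Cy5, against the channel labels. In the channel labelled xylose, 5 of 6 xylose use genes were lower and 0 higher, and all 4 Entner-Doudoroff genes were higher. With sciP, these values argue against the channels as labelled. Of the 2 readings they leave the exchange on both depletion arrays. It was not checked against a record of the labelling, and the titles do not say that they give a ratio of dyes.

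Flagellar and CtrA-activated genes stood on opposite sides of the dyes in the 2 experiments. A dye effect shared by all 4 arrays would move a gene the same way on Cy5 over Cy3, while 27 of 28 flagellum genes were past the threshold on opposite sides and 0 on the same side, which argues against it for these genes; it stays open for genes lower in Cy5 in both experiments (127 against 102 for independent lists), and the Spearman correlation over all genes was only -0.10. Probe GC content is argued against by the flagellum median on overexpression, which was -1.69 both before and after a GC correction. A different share of cells at another cell cycle stage stays open: the early stalked phase markers had a median of -0.22 on overexpression, with members from -1.22 to 0.44, and so decide nothing there. On depletion 3 of 4 markers were lower in Cy5 and 0 higher (median -0.37), opposite to the flagellum list. The markers were not called as a list with median centring in place of loess. The level of sciP RNA, the biological explanation the design names, stays open beside a different share of cells.

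CC0823 and CC0824 rose with sciP on overexpression. Induction of the chromosomal xylose operon is argued against by CC0819 to CC0822, whose median was -0.023. Cross-hybridisation of sciP RNA would lower them with sciP on depletion: CC0824, at 0.11, and the near upstream probes and the first coding probe of CC0823, with a median of 0.083, argue against it there; the last 2 coding probes of CC0823 fell (-0.78 and -5.33, median -3.06) and leave it open there, since the probes upstream of CC0822 fell too (-4.87). Extra copies of the xylose promoter region on the plasmid may account for the rise: the 4 probes next upstream of CC0823 had a median of 5.84, against 0.80 for the 4 probes farther upstream. The rise also ended within CC0823: the 6 probes in its 3' part, upstream of CC0822, had a median of 0.061 on overexpression (from -0.011 to 0.219). The extent of the plasmid's insert and the content of the empty vector are not given in the sources used here.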

How the results depend on the processing

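The probes overlapping the start codon, all sense probes of a window, the turned depletion sign and the crossed pairing were chosen after seeing the data. The value table gave the same counts as the software's log ratio: 404 genes changed on depletion (932 in the report), 559 on overexpression (1556), 43 opposed with the labels as written (194), a correlation of 0.38 (0.42) and 5 lists called on overexpression (3). Median centring in place of loess gave 408, 580, 43, 0.39 and 5. Of those calls, 402 and 403 on depletion and 554 and 574 on overexpression were among those of the report. Scaling between arrays gave 969 genes on overexpression. The cause of these moves was not tested. Turning the depletion sign gave 346 opposed genes and a correlation of -0.42 by construction. The other counts of opposed genes and correlations between experiments in this paragraph take the labels as written. The 346 genes on opposite sides of the dyes were not counted again under the other settings. With an estimated correlation camera called 0 lists in each experiment, against 7 and 3. At an unadjusted p under 0.05 there were 2 and 0. That test has only the 2 residual degrees of freedom of the fit, so few lists could pass. It does not decide whether correlation between genes undoes the list calls. With 1 array left out, the lone array being assumed to vary like the other experiment's, genes changed ranged from 613 to 1122 on depletion and from 1181 to 1555 on overexpression, opposed genes from 116 to 197, the correlation from 0.40 to 0.43, and lists called from 6 to 7 and from 3 to 4.

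Of 166 named gene values past the threshold, 109 stayed past it with the same direction under all 20 settings run for single genes; the 2 filters on dim probes removed nothing and count among these. Including all sense probes brings in bases of neighbouring genes by construction. It reversed sciP (1.43 on depletion, -0.98 on overexpression), fliF (-0.55, 0.18) and parC (0.0020, -0.20), on depletion CC0824 (-0.23) and recN (0.095), and on overexpression xylB (0.26), dnaA (-0.25), CC2948 (-0.064), rpmG (-0.12), rplK (0.21), rpsB (-0.12) and zwf (-0.22). It also called the pilus list on overexpression (adjusted p = 0.0432) and, on depletion, respiration (0.0158) and the cell cycle regulators (0.0277), and not the early stalked phase markers (0.163). Probes overlapping the start codon reversed recN on depletion (0.25). For ccrM on depletion, not called with both arrays, leaving out the first array gave 0.41 and leaving out the second gave -0.45.

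The replicate number as a block gave 820 genes on depletion, 1433 on overexpression and 159 opposed with the labels as written. It gave 7 and 4 lists, the added list being the cell cycle regulators. The numbers did not pair the arrays: the difference of replicate 1 and 2 correlated between experiments at -0.14 across genes. A crossed pairing gave 1080 and 1741 genes. Slide or scan as a block was not run, since each experiment had its own. All 43979 non-control spots were flagged well above background in both channels on all 4 arrays. The flag therefore cannot show whether dim signals limited the calls.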

Other observations

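Runs of at least 3 neighbouring locus tags, all changed by at least 2-fold the same way, were sought after the data were seen. CC0429 to CC0440, 12 genes without a symbol, were higher in the channel with less sciP RNA on depletion (median 1.41, from 1.09 to 3.42), and 11 of them, CC0430 to CC0440, fell on overexpression (median -1.43, from -2.36 to -1.16). CC2944 to CC2950, which hold the pilus genes cpaB and CC2948, had a median of 1.52 on depletion and -0.99 on overexpression, where they ranged from -1.94 to 0.62. CC0232 to CC0234, with pseB and pseC, genes of pseudaminic acid synthesis, had medians of 2.42 and -1.49. CC1456 to CC1462, with the flagellin genes fljK and fljL, had medians of 1.79 and -1.76. CC3144 to CC3148 had medians of 1.95 and -0.67, with overexpression values from -1.66 to -0.0053. In all there were 8 such runs with 43 genes on the higher side on depletion, 3 with 10 genes on the lower side, and 6 with 28 genes that fell on overexpression.

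Other runs and genes followed this opposed pattern only in part or not at all. CC0681 to CC0684 fell on overexpression (median -2.25) with values from -0.18 to 0.28 on depletion. CC2026 to CC2029 fell with a median of -1.30, down to -2.84 for thiC, a gene of thiamine synthesis; on depletion CC2026 was higher in Cy5 at 1.85, while the other 3 genes lay between -0.37 and -0.12. CC0167 (-3.89 and -3.40), CC3501 (-3.53 and -2.05), CC1777 (-2.75 and -1.49) and CC1697 (-2.30 and -1.21) were lower in Cy5 in both experiments. Of the 81 genes that were higher on depletion and lower on overexpression by at least 2-fold, 58 are in no list and 53 have no symbol. Only 727 of all 3595 genes have a symbol, and the lists were filled by symbol or locus tag. Absence from the lists therefore does not show what these genes do.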
